A study of Mus musculus with 6 samples.

How the data were processed

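Whole-eye RNA of mice at postnatal day 21 was sequenced from 6 samples, 3 labelled C57BL/6 wild type and 3 labelled BC027072 knockout. Per the labels, the molecule was total RNA prepared with standard Illumina protocols. No strand, read length, sequencing date, batch or sex was given. The labels do not say whether the replicates are separate animals, so the p-values measure the spread between these samples. Per the submitters' processing notes, TopHat2 2.0.12, Cufflinks 2.2.1 and Cuffdiff 2.2.1 were used with the mouse genome build mm9. All positions are mm9 positions from the authors' files, with starts counted from 1. The reference that was available is a later build, so no coordinate, exon or gene structure was taken from it.

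Per the file headers, the authors deposited estimated fragment counts per gene and library, and the same kind of estimated counts split between the isoforms of each gene. These estimated counts had not been scaled: their totals ran from 5695530 to 21815950 fragments per library. Of the gene values, 98.5% were whole numbers within a tolerance of 1e-06, and of the isoform values 71.7%, so all were rounded before use. The authors also deposited FPKM (fragments per kilobase of transcript, scaled to library size) for the same genes and isoforms, which carry the authors' own scaling between libraries. The FPKM differed from CPM by more than a scaling per library: over 11008 genes the SD of the log2 ratio was 0.357 and 0.303 in wild type replicates 2 and 3 and 0.0679 to 0.169 in the other libraries. The cause is not known, and FPKM set the isoform filter and the limma alternatives. The deposited gene comparison by the authors holds a log2 fold change of knockout over wild type FPKM, a p-value and an adjusted q-value per gene. Transcript lengths were taken from the deposited isoform table. In the replicate tables the libraries of each genotype are numbered from 0, while the labels number the samples from 1. They were read in order as replicates 1 to 3. Which labelled sample of a group each library is was not stated, so the numbers only name libraries, and the tests rely on the group alone, apart from the alternative with a replicate block. The deposited fold change was missing or infinite for some genes, none of them among the genes tested here.

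Of 22558 genes in the table, 18586 had a fragment in some library. The software had failed to estimate 7 genes and 12 isoforms in some library, and these were left out because their deposited values are set to 0. A spreadsheet had turned 25 gene symbols into date numbers. Such genes were tested and counted, and were not named. No replicate value column was left unused.

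The design fixed before the data were examined called for limma on FPKM, with a switch to edgeR if the files held fragment counts. They did, so the gene test was edgeR 4.0.16 (R 4.3.3) on the rounded counts with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood F test of knockout minus wild type over all 6 libraries with no other term. The filter left 14919 genes. Genes past a Benjamini-Hochberg adjusted p of 0.05 were called. Isoforms were tested in the same way where their mean FPKM over all 6 libraries was at least 1, which left 16288 isoforms. A fold change is given as log2 of knockout over wild type with its standard error, computed as the size of the log2 fold change divided by the square root of F. Where few fragments represent a group, this value can be smaller than counting error alone, as for BC027072 and Edn2. Group levels are means with SD in CPM (fragment counts scaled to library size, with TMM factors), n = 3. A fall in a gene that 1 to 3 fragments represent in a group is given as a ratio of fragments with a 95% exact (Clopper-Pearson) interval, which covers counting error only.

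A set of 35 gene lists was written before the data were examined. They cover rod, outer segment and cone genes, the photoreceptor cilium, actin assembly, the other retinal cell types, gliosis, immune cells and signals, stress, the other tissues of the eye, blood, metabolism, the circadian clock, sex-linked genes and strain background. Lists with at least 5 tested members, 32 in all, were tested with camera of limma 3.58.1 with its preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move one way on balance and does not compare the list with other genes. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone.

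The genes named in the text follow a rule fixed before the data were examined. It takes BC027072, the 12 largest rises and 12 largest falls among called genes whose 3 knockout values all lie beyond the 3 wild type values, and up to 4 members of each list with the smallest p. It always takes Gnat1, Opn1sw, Opn1mw, Crx, Gfap, Edn2, Fgf2, Aif1, Rpe65 and Nnt, and for isoforms the 3 largest rises and falls. Predicted genes and rows without a gene symbol were counted and not named. Some genes that the rule takes are not reported here. The text says where a gene outside the rule was chosen after its values were seen.

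Genes starting within 10 Mb of BC027072 were compared with all other tested genes by a two-sided Fisher exact test. Calls were compared with the genes that the authors' table marks as significant. The sex of each library was read from Xist and 4 Y-linked genes and was used only in alternatives added after the data were examined.

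The gene test was first run on simulated counts for 14839 genes with the means and library sizes of these samples. Of 50 genes changed at each size it recovered 32% at 1.25-fold, 76% at 1.5-fold, 86% at 2-fold and 100% at 4-fold, and 14 of its 161 calls were false. In the simulated list test, the list shifted by 0.3 on the log2 scale was called, and none of the other lists among 31 was. Its genes were drawn independently, while in the real data the estimated correlation reached 0.741, in the lens list. The simulation thus does not show how often lists of correlated genes are called falsely with the preset correlation. No pair of libraries in a group was a copy of another: the chi-square per degree of freedom between replicates ran from 2.99 to 9.52.

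Alternatives planned before the data were examined were limma on FPKM (pseudocounts 1 and 0.1, quantile and median-ratio scaling, sample weights, robust), no filter, a mean FPKM of at least 5, the replicate number as a block, DESeq2 1.42.0, its size factors in edgeR, each library left out in turn, other windows around the targeted gene and the authors' own comparison. Those added afterwards were the sex of the library as a covariate, the Xist-positive libraries alone, libraries thinned to the smallest total, limma on log2 CPM of the counts, and limma on FPKM with the block.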

Results

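The data were estimated fragment counts for genes and isoforms in 6 whole-eye RNA libraries from mice at postnatal day 21, 3 wild type (C57BL/6) and 3 BC027072 knockout. BC027072 is the mouse ortholog of human C2orf71 (PCARE), a photoreceptor ciliary gene mutated in retinitis pigmentosa. The wild type libraries held 21815950, 14341398 and 8441944 fragments, and the knockout libraries 8444913, 5695530 and 10343820. Correlations of log2 CPM across genes were 0.987 to 0.992 within a group and 0.982 to 0.986 between groups, and genes are not independent replicates. The first principal component, 40.2% of the variance, parted the genotypes. The second, 19.7%, set knockout replicate 2 apart from the other knockout libraries.

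The libraries also differed in sex. All 3 wild type libraries and knockout replicate 2 held Xist, the RNA of the inactive X chromosome (17749, 13656, 7763 and 5905 fragments), with 7, 2, 1 and 2 fragments of 4 Y-linked genes. Knockout replicates 1 and 3 held 2047 and 2957 Y-linked fragments and 11 and 18 Xist fragments. Only Xist of the sex-linked list was tested, with a log2 fold change of −1.45 (adjusted p = 0.552). The male libraries were thus all knockout, and for each gene group with passing members it is stated which or how many also passed with the sex of the library as a covariate, an alternative chosen after the data were examined. Its power was low, since 1 knockout library then carries the comparison within a sex. Of the 931 genes that passed without it, 230 passed with it, and all 931 kept their sign. The knockout library that carries that comparison also had a part in calling the 931, so the kept sign says little about sex. The 9 genes of the list for strain background included 1 that rose, Glo1, a detoxifying enzyme (0.43 ± 0.07, adjusted p = 0.000656), and none that fell, against 1 and 1 adjusted over the list alone. Glo1 passed with sex as a covariate. Nnt, lost in the C57BL/6J substrain, had a log2 fold change of −0.14 ± 0.10 (adjusted p = 0.487). The list was not past the threshold (adjusted p = 0.711).

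BC027072 (NM_146082, chromosome 17, 72092895 to 72102225 in mm9) was nearly undetected in all 3 knockout libraries. Its fragments numbered 5854, 3667 and 2251 in the wild type libraries and 3, 2 and 3 in the knockout libraries. Corrected for library size, knockout over wild type was 0.119% (95% exact interval 0.0515% to 0.235%, counting error only). The level was 269 ± 9.32 CPM in wild type and 0.326 ± 0.0375 CPM in knockout (SD, n = 3 each), or 53.9 ± 7.59 and 0.0639 ± 0.00908 FPKM. The edgeR log2 fold change was −9.66 (adjusted p = 4.81e-17), which at so few fragments depends on the prior count of the fit. Its SE computed from F, 0.13, is smaller than the counting error that the exact interval shows. For this gene each of the 6 libraries matched its genotype label.

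What loss of BC027072 changed in the eye was then asked across all genes. Edn2, a vasoactive endothelin peptide that stressed photoreceptors are known to release, rose most, from 0.587 ± 0.459 to 31.0 ± 1.30 CPM (SD, n = 3 each; log2 fold change 6.04 ± 0.22, SE; adjusted p = 1.47e-10). Fgf2, a growth factor that protects photoreceptors, rose from 2.50 ± 0.190 to 15.2 ± 0.191 CPM (2.63 ± 0.14). Nrl, the transcription factor that specifies rods, fell from 905 ± 23.5 to 446 ± 10.7 CPM (−1.02 ± 0.06). In this text a value with an error in parentheses is a log2 fold change of knockout over wild type ± SE from edgeR, with 3 libraries per group. Of 14919 genes tested with edgeR, 431 were higher and 500 lower in the knockout. Most changes were small: 63 of the higher and 27 of the lower genes moved at least 2-fold, and the median sizes were 1.42-fold and 1.31-fold.

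With limma on log2(FPKM + 1), the test planned for files without counts, 10 genes were higher and 3 lower, and with the sex of the library as a covariate 91 and 144. Without wild type replicate 2, knockout replicate 1 or knockout replicate 2, the higher genes numbered 271, 277 and 275, and without knockout replicate 2 the lower genes numbered 315.

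**Figure D1:**
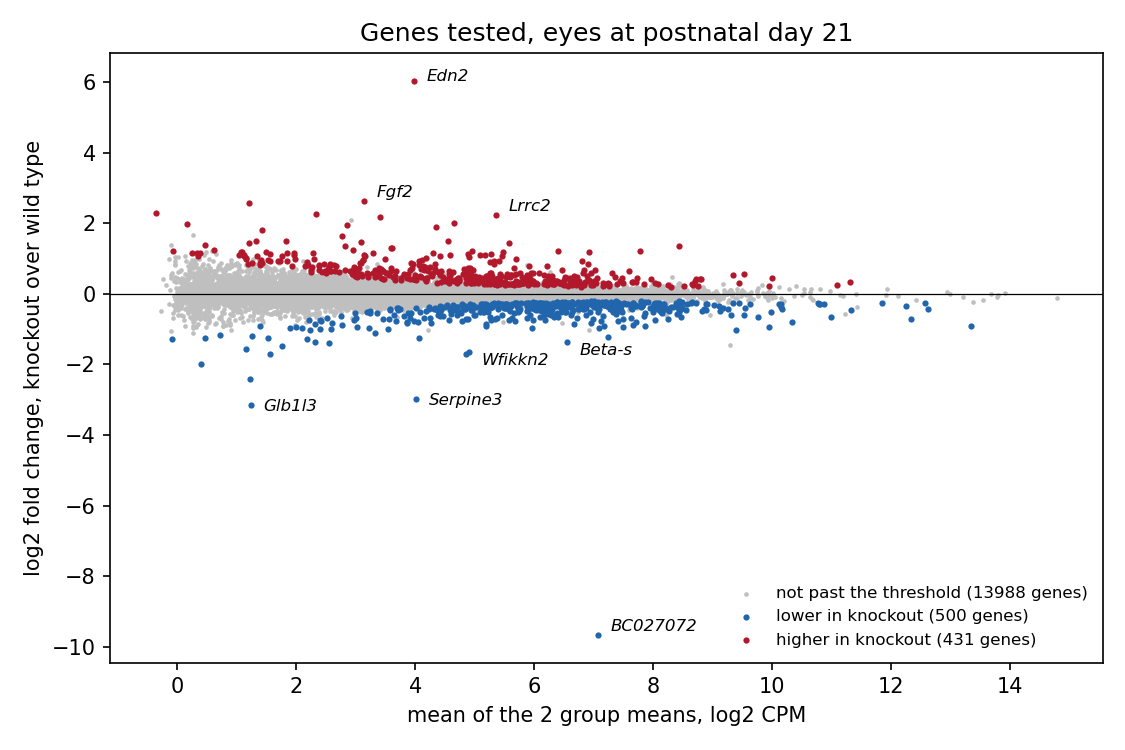
Log2 fold change of knockout over wild type for each tested gene (vertical axis) against the mean of both group means (log2 CPM, horizontal axis), 3 libraries per group. Red points are the 431 higher genes, blue points the 500 lower genes and grey points the genes that did not pass, with BC027072 at −9.66 and Edn2 at 6.04.

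Among the largest rises after Edn2 and Fgf2 were Cfi, a protease that inactivates complement (2.57 ± 0.30, adjusted p = 5.27e-05), Trim43c (2.30 ± 0.39, adjusted p = 0.00159), and Bcl3, a regulator of NF-kappaB (2.26 ± 0.20, adjusted p = 2.60e-06). Lrrc2, a leucine-rich repeat gene, rose from 14.5 ± 1.39 to 67.2 ± 1.93 CPM (2.23 ± 0.08, adjusted p = 1.67e-10). Cebpd, a transcription factor of the acute-phase response, rose (2.02 ± 0.17, adjusted p = 1.62e-06), as did Btc, a ligand of the epidermal growth factor receptor (1.89 ± 0.11, adjusted p = 2.49e-08). Fhad1 (1.95 ± 0.16), the immunoglobulin receptor gene Fcamr (1.82 ± 0.24) and the class I histocompatibility gene H2-Q7 (1.97 ± 0.34, whose reads paralogs may share) completed the rises with Nudt6 (2.17 ± 0.15, adjusted p = 2.73e-07). Nudt6 and Fgf2 lie 153 bases apart in the files' loci on chromosome 3 (Fgf2 37247575 to 37303752, Nudt6 37303906 to 37318512) and are known as an antisense pair. The strand of the reads is not stated, so their signals may not be separate. Edn2 lies on chromosome 4 (119834029 to 119839965). Trim43c did not pass with sex as a covariate. In the Xist-positive libraries alone, with 1 knockout library, the log2 fold changes were 2.21 for Trim43c and 2.34 for H2-Q7.

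The largest falls after BC027072 were Glb1l3, a beta-galactosidase-like gene (4.26 ± 0.393 to 0.449 ± 0.266 CPM, −3.14 ± 0.32, adjusted p = 1.13e-05), and Serpine3, a serpin protease inhibitor gene (29.0 ± 6.93 to 3.42 ± 1.27 CPM, −2.99 ± 0.22, adjusted p = 5.16e-07). Wfikkn2, which encodes an inhibitor of myostatin, fell (−1.66 ± 0.13, adjusted p = 8.02e-07), as did Rasl11a, a small GTPase gene (−1.48 ± 0.24). The other falls were Iqcj-schip1 (−2.42 ± 0.38), the muscle ankyrin repeat gene Ankrd2 (−1.99 ± 0.38), the Wnt ligand gene Wnt9b (−1.57 ± 0.29), Agxt2l1 (−1.39 ± 0.23) and the uroplakin gene Upk3b (−1.35 ± 0.22). The globin genes Hba-a1 (−1.69 ± 0.29) and Beta-s (135 ± 29.4 to 52.8 ± 11.7 CPM, −1.37 ± 0.15) fell too, though paralogs may share their reads. With sex as a covariate Iqcj-schip1, Ankrd2, Hba-a1, Wnt9b, Rasl11a and Agxt2l1 did not pass, and Hba-a1 did not pass in DESeq2 either.

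**Figure D2:**
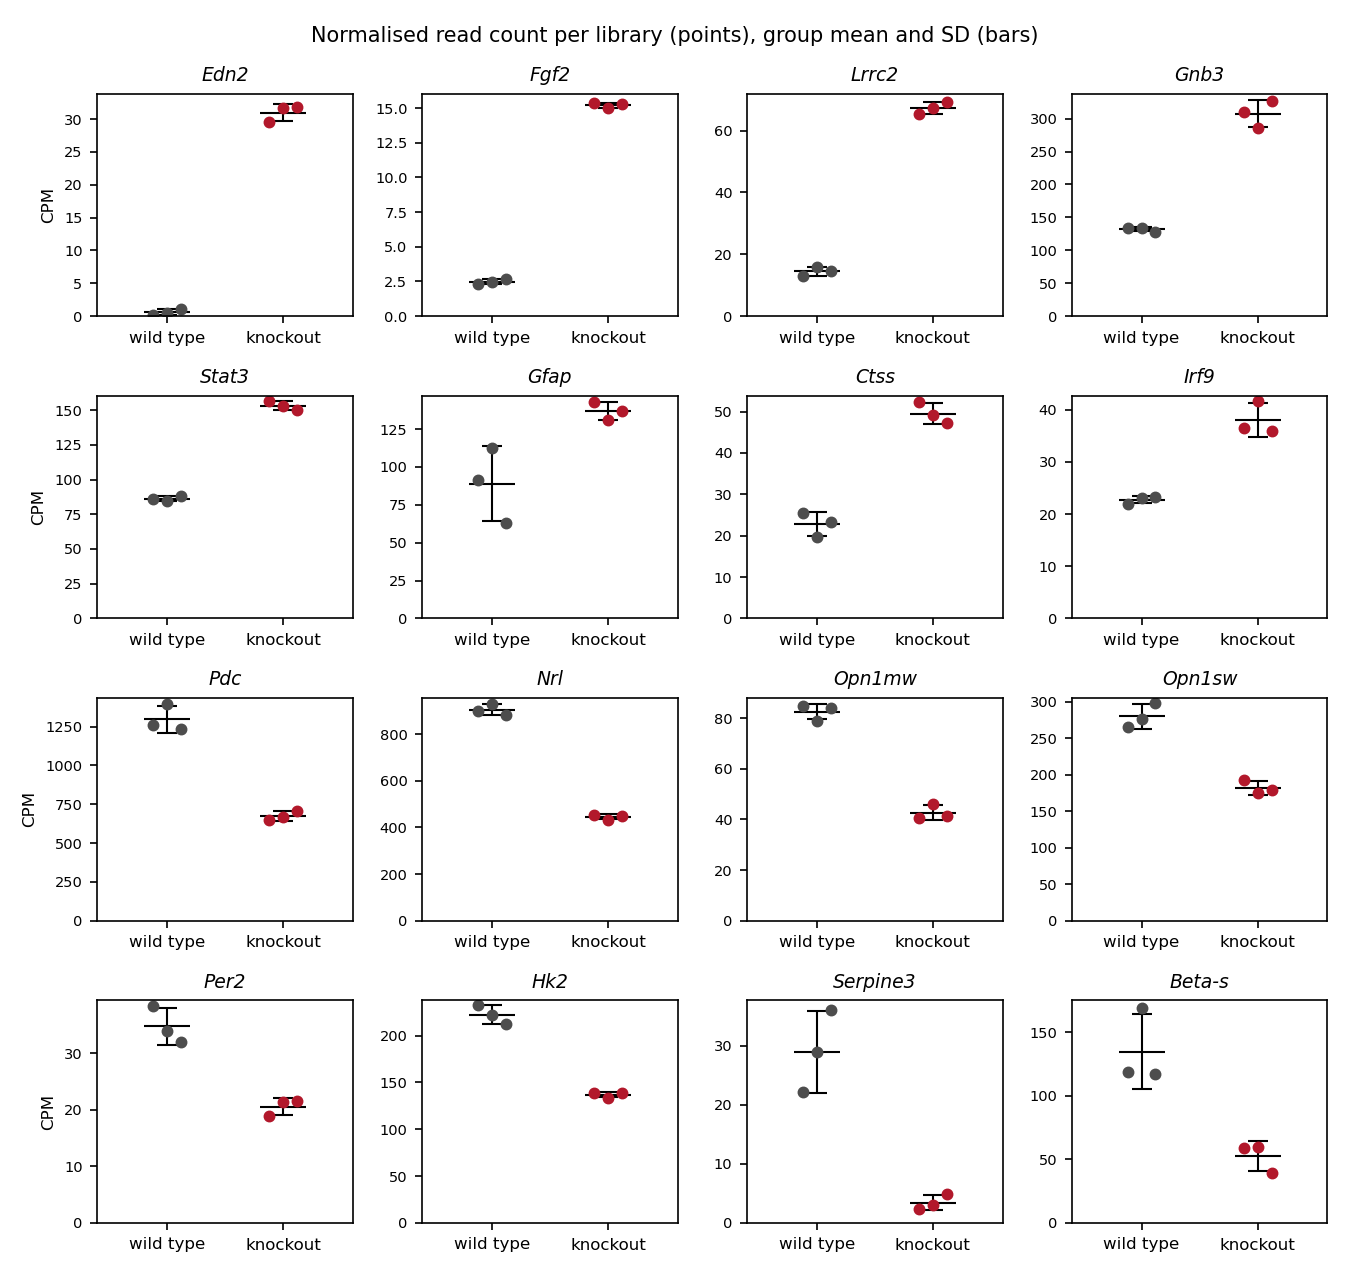
Normalised read count (CPM, linear vertical axis from 0) of 16 genes in each library, wild type in grey and knockout in red, with the mean and SD of 3 libraries as bars. Edn2 averaged 0.587 CPM in wild type and 31.0 in knockout, and Nrl 905 and 446.

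Rod genes fell together. Of 19 rod phototransduction genes, 16 fell, 1 rose and 2 did not pass (18 fell and 1 rose adjusted over the list alone). Pdc, which encodes the transducin-binding protein phosducin, fell (−0.95 ± 0.07, adjusted p = 3.84e-07), as did Gnat1, the rod transducin alpha subunit (−0.70 ± 0.07, adjusted p = 1.19e-05) and Gucy2f, a guanylate cyclase gene (−0.69 ± 0.07). The member that rose was Sag, rod arrestin, from 2249 ± 51.5 to 2830 ± 82.8 CPM (0.33 ± 0.06, adjusted p = 0.00249), named after its value was seen. The median log2 fold change was −0.45 and the list was lower than other genes by camera (adjusted p = 6.63e-26, and adjusted p = 0.0216 with an estimated correlation). With sex as a covariate, 10 of the 17 passing members passed, Pdc, Gnat1 and Gucy2f among them and Sag not.

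Of 27 genes of the outer segment and of photoreceptor transcription factors, 21 fell, 2 rose and 4 did not pass (22 and 2 adjusted over the list alone). Nrl fell to 49.3% of wild type, and the nuclear receptor gene Esrrb fell (−0.94 ± 0.06, adjusted p = 5.40e-08). Rdh12, a retinol dehydrogenase gene, fell (−0.81 ± 0.06), as did Crx, a transcription factor of rods and cones (−0.39 ± 0.06, adjusted p = 0.00105). Samd7, a photoreceptor transcriptional repressor (0.49 ± 0.06), and Impg2, a proteoglycan of the matrix around photoreceptors (0.44 ± 0.06), rose, and both are named after their values were seen. The median was −0.42 (camera adjusted p = 4.96e-34, and adjusted p = 0.0216 with an estimated correlation). With sex as a covariate 17 of the 23 passing members passed, Nrl, Esrrb and Rdh12 among them and Crx not.

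Most cone genes that passed fell, and 1 rose. Of 16 tested, 9 fell, 1 rose and 6 did not pass (9 and 1 adjusted over the list alone). The middle-wavelength opsin gene Opn1mw fell (−0.96 ± 0.07, adjusted p = 3.84e-07), as did cone arrestin Arr3 (−0.75 ± 0.07, adjusted p = 4.87e-06) and the short-wavelength opsin gene Opn1sw (−0.62 ± 0.07, adjusted p = 1.81e-05). Gnb3, the transducin beta subunit of cones, rose from 132 ± 3.26 to 308 ± 20.5 CPM (1.22 ± 0.06, adjusted p = 1.05e-08). The median was −0.32 (camera adjusted p = 1.38e-07, and adjusted p = 0.0451 with an estimated correlation). With sex as a covariate 5 of 10 passing members passed, including these 4.

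BC027072 encodes a ciliary protein, so genes of the photoreceptor cilium and of actin assembly were asked about as groups. Of 39 cilium genes 11 fell, 3 rose and 25 did not pass (16 and 3 adjusted over the list alone). Fam161a, a retinitis pigmentosa gene, fell (−0.56 ± 0.08). The rises were the Bardet-Biedl syndrome gene Arl6 (0.93 ± 0.08, adjusted p = 1.58e-06), the Usher syndrome gene Pcdh15 (0.46 ± 0.07) and the ciliary kinase gene Mak (0.27 ± 0.06), the last named after its value was seen. The median was −0.10 (camera adjusted p = 0.00562, but adjusted p = 0.285 with an estimated correlation), and 4 of 14 passing members passed with sex as a covariate. Of 25 genes of the WAVE and Arp2/3 complexes, 1 fell, Wasf3 (−0.27 ± 0.07, adjusted p = 0.0219), which is also the count adjusted over the list alone. The list did not pass (adjusted p = 0.568), and Wasf3 did not pass without wild type replicate 2 (adjusted p = 0.0822), wild type replicate 3 (0.0503), knockout replicate 2 (0.117) or knockout replicate 3 (0.0874), or with sex as a covariate.

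**Figure D3:**
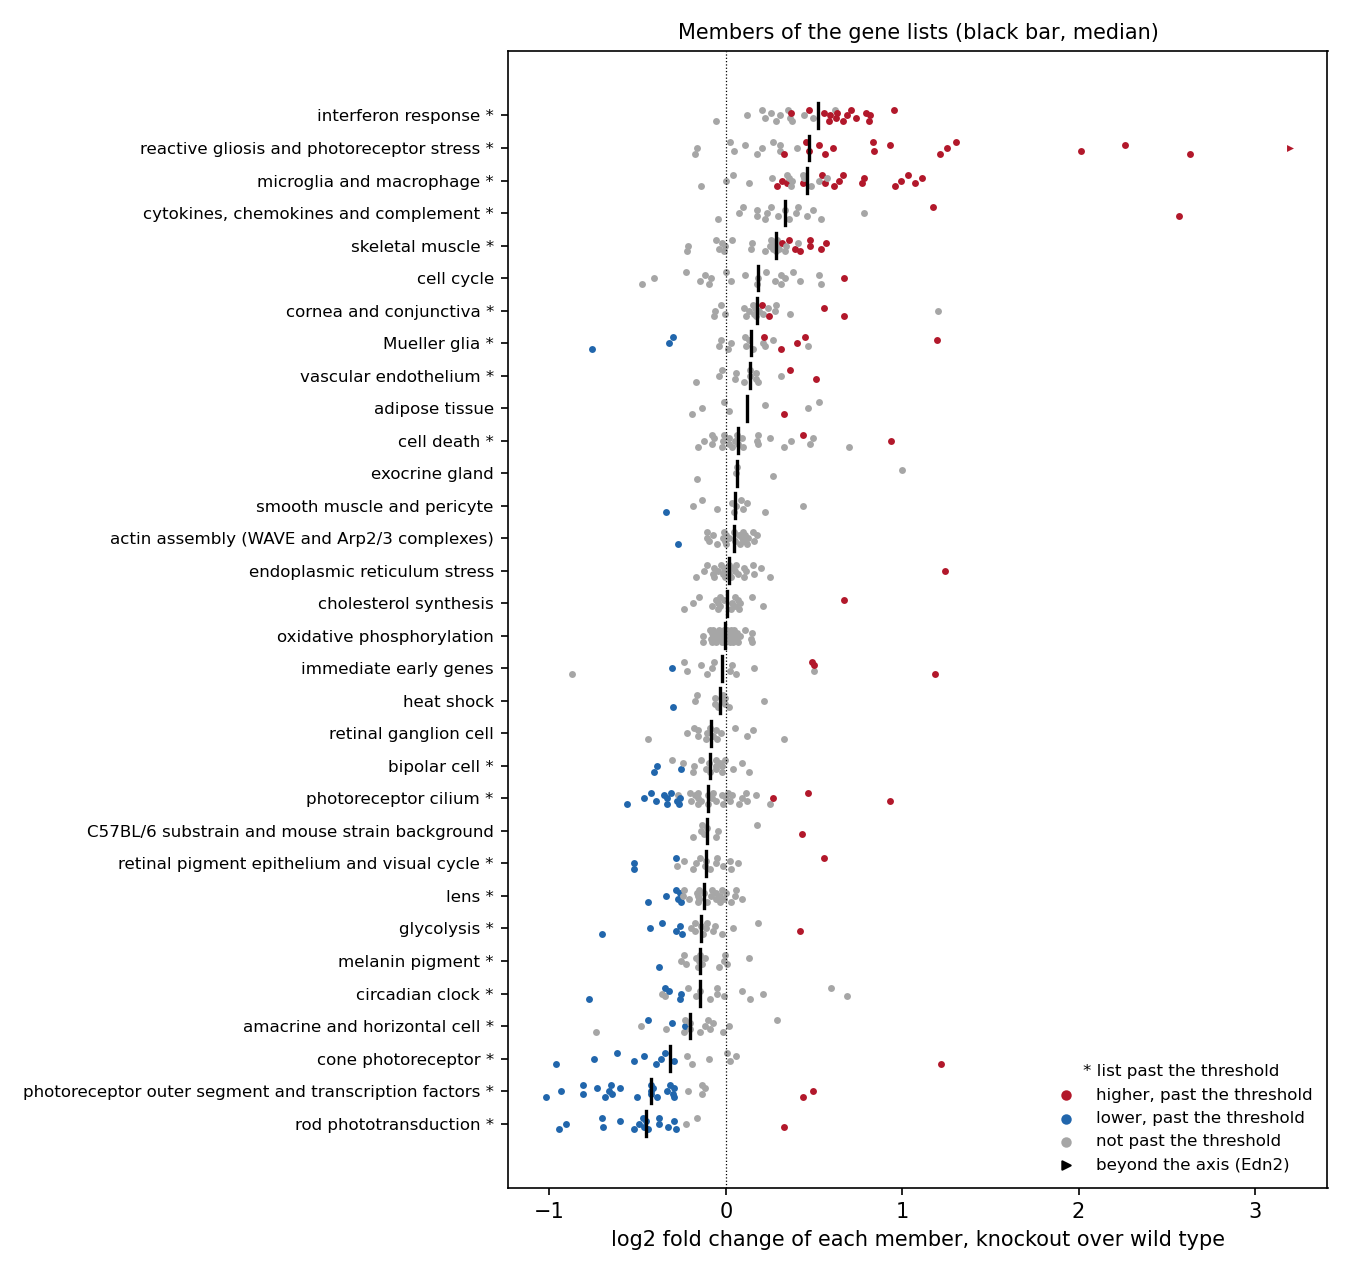
Log2 fold change of knockout over wild type (horizontal axis) of each tested member of the 32 lists tested, red where it rose, blue where it fell and grey where it did not pass, with the list median as a black bar and an asterisk at the 20 lists past the threshold with the preset correlation. The medians run from −0.45 for rod phototransduction to 0.52 for the interferon response.

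The other retinal neurons moved less. Of 21 bipolar cell genes, 3 fell and 18 did not pass, and the same count held adjusted over the list alone: the bipolar markers Pcp2 (−0.39 ± 0.09, adjusted p = 0.0114), Prkca (−0.25 ± 0.06, adjusted p = 0.0233) and Bhlhe23 (−0.40 ± 0.11, adjusted p = 0.0303). The list median was −0.09 (camera adjusted p = 0.0180, but adjusted p = 0.133 with an estimated correlation and 0.0627 without wild type replicate 2). Of 18 amacrine and horizontal cell genes, 3 fell (4 adjusted over the list alone): the gap junction gene Gjd2 (−0.44 ± 0.06), the glycine transporter gene Slc6a9 (−0.31 ± 0.07) and Gad1, which makes the transmitter GABA (−0.23 ± 0.06, adjusted p = 0.0351). Its median was −0.20 (adjusted p = 0.00151, but adjusted p = 0.133 with an estimated correlation) and −0.13 in the Xist-positive libraries alone. None of these 6 passed with sex as a covariate. Pcp2 and Prkca did not pass without wild type replicate 2, knockout replicate 2 or knockout replicate 3 (adjusted p = 0.0525, 0.0568 and 0.0768 for Pcp2, and 0.101, 0.0904 and 0.106 for Prkca). With 1 library left out, Bhlhe23 and Gad1 passed only without wild type replicate 3 (otherwise adjusted p = 0.0777 to 0.111 and 0.0524 to 0.131). None of 16 ganglion cell genes passed in edgeR, over all genes tested or adjusted over the list alone, in DESeq2, or in limma on log2(FPKM + 1) or log2 CPM, with 2 at an unadjusted p under 0.05. With sample weights in limma on FPKM, which did not converge, 3 passed: Gap43, Pou4f3 and Sncg, named after their values were seen. That list did not pass (median −0.08, adjusted p = 0.383).

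Mueller glia genes, which mark the main supporting cell of the retina, moved both ways. Of 20, 5 rose and 3 fell (8 and 3 adjusted over the list alone). Crym, a thyroid hormone-binding crystallin, rose (1.20 ± 0.07, adjusted p = 2.49e-08), as did the chaperone clusterin, Clu (0.45 ± 0.07) and the water channel gene Aqp4 (0.40 ± 0.06), and Spc25, a kinetochore gene, fell (−0.76 ± 0.07, adjusted p = 3.36e-06). The remaining passing members, named after their values were seen, were Id2 (0.31 ± 0.06) and Dbi (0.21 ± 0.06), which rose, and Car14 (−0.32 ± 0.06) and Glul, glutamine synthetase (−0.30 ± 0.06), which fell. The median was 0.14 (camera adjusted p = 0.00138, but adjusted p = 0.122 with an estimated correlation), and 4 of 8 passed with sex as a covariate.

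Genes of reactive gliosis and photoreceptor stress rose as a group. Of 27, 16 rose and none fell (21 and 0 adjusted over the list alone). Beside Edn2, Fgf2, Cebpd and Bcl3 they included Stat3, a transcription factor of cytokine signalling (86.2 ± 1.77 to 153 ± 3.44 CPM, 0.83 ± 0.06, adjusted p = 1.70e-07), and Osmr, the oncostatin M receptor gene (0.93 ± 0.08, adjusted p = 1.38e-06). Gfap, the intermediate filament of reactive glia, rose from 89.1 ± 24.8 to 137 ± 6.02 CPM (0.61 ± 0.13, adjusted p = 0.00985). Socs3, an inhibitor that Stat3 induces (1.30 ± 0.12), and the cytokine gene Lif (1.25 ± 0.29) also rose, both named after their values were seen. The median was 0.47 and the list was higher than other genes (camera adjusted p = 4.47e-48, and adjusted p = 0.00242 with an estimated correlation). With sex as a covariate 9 of the 16 passed. Gfap did not pass then, in DESeq2 or without knockout replicate 1 (adjusted p = 0.0541).

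Microglia and macrophage genes rose as well. Of 30, 16 rose and none fell (22 and 0 adjusted over the list alone). Ctss, a lysosomal protease gene, rose (1.11 ± 0.09, adjusted p = 1.62e-06), as did Mpeg1, a pore-forming protein of macrophages (0.77 ± 0.11), the fractalkine receptor gene Cx3cr1 (0.64 ± 0.11) and the complement gene C1qb (0.56 ± 0.10). The class II histocompatibility genes Cd74 (0.99 ± 0.18) and H2-Aa (1.07 ± 0.20), named after their values were seen, rose too. Aif1, the microglial marker IBA1, had a log2 fold change of 0.36 ± 0.34 (adjusted p = 0.643). The median was 0.46 (camera adjusted p = 3.68e-19, but adjusted p = 0.122 with an estimated correlation). With sex as a covariate 2 of the 16 passed, Ctss and Mpeg1, and the median in the Xist-positive libraries alone was 0.41.

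Of 28 interferon response genes, 15 rose and none fell (18 and 0 adjusted over the list alone). The class I histocompatibility genes H2-K1 (0.80 ± 0.08, adjusted p = 1.35e-05) and H2-D1 (0.59 ± 0.08) rose, and paralogs may share their reads. Irf9, a transcription factor of interferon signalling, rose too (0.74 ± 0.08, adjusted p = 3.99e-05). The median was 0.52 in all libraries and also in the Xist-positive libraries alone (camera adjusted p = 4.19e-17, but adjusted p = 0.133 with an estimated correlation), and 6 of the 15 passed with sex as a covariate. Of 19 genes of cytokines, chemokines and complement, 2 rose, Cfi and the inflammasome protease gene Casp1 (1.17 ± 0.30, adjusted p = 0.0253), and none fell (6 and 0 adjusted over the list alone). That list was higher too (median 0.34, adjusted p = 2.64e-06, but adjusted p = 0.102 with an estimated correlation), with a median of 0.17 in the Xist-positive libraries alone. Casp1 did not pass when any library but wild type replicate 3 was left out (adjusted p = 0.0601 to 0.105) or with sex as a covariate, and Cfi did pass with it.

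Cell death and stress lists moved little. Of 27 cell death genes 2 rose (3 adjusted over the list alone), the tumour necrosis factor receptor gene Tnfrsf1a (0.44 ± 0.09, adjusted p = 0.00762) and Bbc3, which encodes the apoptosis inducer PUMA (0.94 ± 0.26, adjusted p = 0.0431). The list median was 0.07 (adjusted p = 0.0246, but adjusted p = 0.133 with an estimated correlation, 0.0574 without wild type replicate 2 and 0.0653 without knockout replicate 1). The list also did not pass with sex as a covariate, in the Xist-positive libraries alone, at a mean FPKM of at least 5 or with libraries thinned to the smallest. Tnfrsf1a did not pass without knockout replicate 1 or 2 (adjusted p = 0.0506 and 0.0516), and Bbc3 did not without wild type replicates 2 or 3 or knockout replicates 1 or 2 (adjusted p = 0.0728 to 0.258). Neither passed with sex as a covariate. Of 27 endoplasmic reticulum stress genes only Atf3, a stress-induced transcription factor, rose (1.24 ± 0.16, adjusted p = 0.000127), as adjusted over the list alone, and the list did not pass (adjusted p = 0.433). Of 12 heat shock genes 1 fell by either count, the chaperone gene Hsp90aa1 (−0.30 ± 0.07, adjusted p = 0.0144; 0.0749 without wild type replicate 2 and 0.0604 without knockout replicate 1), and the list did not pass (adjusted p = 0.345). Of 22 cell cycle genes 1 rose by either count, the proliferation marker Mki67 (0.67 ± 0.12, adjusted p = 0.00187), and the list did not pass (adjusted p = 0.220). Atf3 and Mki67 passed with sex as a covariate and Hsp90aa1 did not.

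The early response, clock and metabolic lists were mixed. Of 16 immediate early genes 3 rose and 1 fell (3 and 2 adjusted over the list alone): Junb (0.49 ± 0.09), Cyr61 (0.50 ± 0.13) and Fosb (1.18 ± 0.33) rose and Btg2 (−0.31 ± 0.07) fell, and none of them passed with sex as a covariate. With 1 library left out, Cyr61 passed only without wild type replicate 1 (otherwise adjusted p = 0.0510 to 0.141) and Fosb only without wild type replicates 1 or 3 (otherwise 0.0756 to 0.176), while Btg2 did not pass without knockout replicate 2 (0.0716). The list did not pass (adjusted p = 0.568). Of 19 circadian clock genes 5 fell and none rose (9 and 2 adjusted over the list alone). The clock repressor gene Per2 fell (−0.77 ± 0.10, adjusted p = 8.26e-05), and Cry1 (−0.35 ± 0.08), Usp2 (−0.32 ± 0.07), Dbp (−0.26 ± 0.06) and Tef (−0.26 ± 0.06, named after its value was seen) fell less. The median was −0.15 (adjusted p = 0.00521, but adjusted p = 0.133 with an estimated correlation), and 1 of the 5, Per2, passed with sex as a covariate. The labels give no hour of collection. Cry1 did not pass without wild type replicate 2 or knockout replicate 1 (adjusted p = 0.0687 and 0.0633), Usp2 without wild type replicate 1 or knockout replicate 1 (0.0554 and 0.0686) and Dbp without knockout replicate 2 (0.0746).

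Of 19 glycolysis genes 6 fell and 1 rose (9 and 2 adjusted over the list alone). Hk2, the hexokinase of photoreceptors, fell (−0.70 ± 0.06, adjusted p = 1.62e-06), as did the enolase gene Eno1 (−0.43 ± 0.08) and the lactate exporter gene Slc16a3 (−0.36 ± 0.08, adjusted p = 0.0520 without knockout replicate 2), while the hexokinase gene Hk1 rose (0.42 ± 0.07). The median was −0.14 (camera adjusted p = 0.000284, but adjusted p = 0.217 with an estimated correlation), and 2 of the 7 passed with sex as a covariate. None of 41 oxidative phosphorylation genes passed in edgeR by either count, in DESeq2, or in limma on log2(FPKM + 1) or log2 CPM, with 2 at an unadjusted p under 0.05 (list median −0.01, adjusted p = 0.940). With sample weights in limma Ndufb10 and Cox6b1 passed (adjusted p = 0.0388 and 0.0431), and the authors' comparison marked Cox8a, named after its value was seen. Of 20 cholesterol synthesis genes 1 rose by either count, the mevalonate pathway kinase gene Pmvk (0.67 ± 0.08), which passed with sex as a covariate, and the list did not pass (adjusted p = 0.633).

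Genes of the other tissues of the eye moved by small amounts. Of 18 genes of the retinal pigment epithelium and visual cycle, 3 fell and 1 rose (6 and 1 adjusted over the list alone). The lactate transporter gene Slc16a1 fell (−0.52 ± 0.06), as did the retinol dehydrogenase gene Rdh10 (−0.52 ± 0.07) and Rpe65, the retinoid isomerase (−0.28 ± 0.07, adjusted p = 0.0231), and the thyroid hormone and retinol carrier gene Ttr rose (0.56 ± 0.06). The median was −0.11 (adjusted p = 0.00680, but adjusted p = 0.133 with an estimated correlation) and −0.17 in the Xist-positive libraries alone, and 3 of 4 passed with sex as a covariate. Sample weights and the robust option of limma do not enter the list test, so they add no separate test of a list. The list did not pass in limma on FPKM without the replicate block, at either pseudocount or scaling (adjusted p up to 0.389). Rpe65 did not pass then, nor without wild type replicate 2 or knockout replicates 1 or 2 (adjusted p = 0.106, 0.102 and 0.128). Of 15 melanin pigment genes 1 fell by either count, the albinism gene Oca2 (−0.38 ± 0.08), with a list median of −0.15 (adjusted p = 0.0233, but adjusted p = 0.133 with an estimated correlation). Oca2 did not pass with sex as a covariate.

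Of 29 lens genes 6 fell and none rose (9 and 0 adjusted over the list alone), among them the crystallin genes Cryga (−0.44 ± 0.07, adjusted p = 0.00115) and Crybb1 (−0.34 ± 0.06, adjusted p = 0.00301), whose paralogs may share reads. The list took 15.3% to 17.7% of the fragments of a library. Its median was −0.12 (adjusted p = 0.00180, but adjusted p = 0.639 with an estimated correlation and 0.156 without wild type replicate 3), and none of the 6 passed with sex as a covariate. Of 22 cornea and conjunctiva genes 4 rose and none fell (7 and 0 adjusted over the list alone): the basal keratin gene Krt14 (0.56 ± 0.11), the mucin gene Muc4 (0.67 ± 0.13), the corneal keratin gene Krt12 (0.25 ± 0.07, adjusted p = 0.0396) and the uroplakin gene Upk1b (0.20 ± 0.06, adjusted p = 0.0470). The median was 0.18 (adjusted p = 7.94e-05, but adjusted p = 0.285 with an estimated correlation), and none of the 4 passed with sex as a covariate. Krt12 passed only without wild type replicate 3 (otherwise adjusted p = 0.0779 to 0.170), and Upk1b did not pass when any library was left out (adjusted p = 0.0622 to 0.209).

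Of 30 skeletal muscle genes 8 rose and none fell (17 and 1 adjusted over the list alone), such as the fast myosin gene Myh4 (0.54 ± 0.09) and the myosin-binding protein gene Mybpc2 (0.57 ± 0.12). In DESeq2 3 of the 30 were called, Mybpc2 not among them. The median was 0.28 (adjusted p = 2.04e-06, but adjusted p = 0.400 with an estimated correlation) and 0.17 in the Xist-positive libraries alone, and none of the 8 passed with sex as a covariate. Of 14 vascular endothelium genes 2 rose and none fell (3 and 0 adjusted over the list alone), the vascular growth factor receptor gene Kdr (0.51 ± 0.06, adjusted p = 7.10e-05) and the adhesion gene Pecam1 (0.36 ± 0.08, adjusted p = 0.0115; 0.0577 without wild type replicate 2). The list median was 0.14 (adjusted p = 0.00483, but adjusted p = 0.376 with an estimated correlation), and Kdr passed with sex as a covariate. The 3 red blood cell genes tested, too few for the list test, all fell by either count: Hba-a1, Hbb-b1 (−1.25 ± 0.15) and the heme synthesis gene Alas2 (to 49.9% of wild type). None of the 3 passed with sex as a covariate. Of 12 smooth muscle and pericyte genes 1 fell, the myosin kinase gene Mylk (−0.34 ± 0.06; 1 and 1 adjusted over the list alone), and of 8 adipose genes 1 rose, the lipase gene Lpl (0.33 ± 0.07, adjusted p = 0.0537 without knockout replicate 2; 2 adjusted over the list alone). Mylk and Lpl did not pass with sex as a covariate, and neither list passed by camera (adjusted p = 0.701 and 0.238). The adipose list was higher in fry (adjusted p = 0.0472). None of 5 exocrine gland genes or 4 bone and cartilage genes passed in edgeR by either count, in DESeq2, or in limma on log2(FPKM + 1), with or without sample weights, or log2 CPM, with 1 and 0 at an unadjusted p under 0.05, and the gland list did not pass (adjusted p = 0.275). The gland gene with an unadjusted p under 0.05 was the lactoferrin gene Ltf (1.00 ± 0.40, adjusted p = 0.172), which the authors' comparison marked as significant (q = 0.00162) and which passed in edgeR without wild type replicate 1.

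The lists came to 20 of 32 past the threshold with the preset correlation, 9 higher and 11 lower. A split of the libraries that mixed the genotypes called up to 15 lists in the same way. With an estimated correlation 4 of the 20 held: rod phototransduction, outer segment and transcription factors, and cone photoreceptor lower, and gliosis and photoreceptor stress higher. In fry, 16 of the 20 held and the adipose list was added, and those that did not hold were lens, cornea, skeletal muscle and endothelium. At a mean FPKM of at least 5 the bipolar and melanin lists did not pass either, nor did the melanin and lens lists with quantile-normalized FPKM.

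Isoforms were compared to ask whether single transcripts moved apart from their genes. BC027072 has 1 isoform in the files, NM_146082 (5006 bases), and it was the isoform that fell most. The isoform NM_007902 of Edn2 rose (5.94 ± 0.46), as did NM_008006 of Fgf2 (2.61 ± 0.12). Of 16288 isoforms tested in edgeR, 91 were higher and 169 lower, from 256 genes. Kirrel, a nephrin-like adhesion gene, had NM_130867 at 893 estimated fragments over the wild type libraries and 2 over the knockout libraries (knockout over wild type 0.395%, 95% exact interval 0.0478% to 1.43%, counting error only; adjusted p = 0.00960), while the gene had a log2 fold change of −0.21 (adjusted p = 0.0908). Gpr19, an orphan receptor gene, showed NM_008157 at 2 fragments in wild type and 75 in knockout (wild type over knockout 1.51%, interval 0.180% to 5.66%; adjusted p = 0.0244), with a gene log2 fold change of 0.12 (adjusted p = 0.713). The isoform of Serpine3, NM_001199945, fell (−3.05 ± 0.32). Isoform NM_180662 of Trappc9, a vesicle tethering gene, fell (−2.01 ± 0.28), and the gene fell less (−0.22 ± 0.06, adjusted p = 0.0320). In 1 of 1966 genes with at least 2 tested isoforms, one isoform rose and another fell: in the kinase gene Map3k7, named after its values were seen, NM_009316 rose (0.52 ± 0.07) and NM_172688 fell (−0.69 ± 0.11). In 11 cases an isoform passed and its gene did not.

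These isoform values are the authors' estimates of how fragments split between overlapping transcripts. For Kirrel and Gpr19, whose genes did not pass, the near-complete moves of 1 isoform may come from that split, which the deposited values cannot settle. Without 1 library at a time the higher isoforms numbered 22 to 37 and the lower 19 to 73, with sex as a covariate 15 and 49, and with the replicate number as a block 3 and 2.

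Genes close to BC027072 were examined because a targeted allele can carry flanking DNA of the stem cell strain. Within 10 Mb on either side 5 of 87 tested genes passed (5.75%), against 925 of 14831 elsewhere (6.24%; odds ratio 0.917, 95% interval 0.289 to 2.24; two-sided Fisher exact p = 1). They were Lbh, a cofactor of transcription (−0.38 ± 0.06), the kinase gene Map4k3 (−0.26 ± 0.06), the interferon-induced kinase gene Eif2ak2 (0.42 ± 0.10) and 2 genes known by predicted or clone names, all chosen after their values were seen. The number of genes limits this comparison, since the interval spans both depletion and enrichment. The histocompatibility genes H2-K1, H2-D1 and H2-Q7, which rose, also lie on chromosome 17 (starts 34132957, 35400039 and 35576100), outside every window used. Whether flanking DNA reached them was not tested.

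The authors' own comparison marked 1001 genes as significant, 458 higher and 543 lower in the knockout. Of these, 672 were also called by edgeR here, all with the same direction. A further 329 were significant for the authors alone and 259 were called here alone. Edn2, Fgf2, Nrl, Opn1mw, Stat3 and Gnb3 were in both sets. In the lens list the authors marked 1 gene, against 6 called here. Of the genes named as past the threshold, those not significant for the authors were Iqcj-schip1, Pcp2, Prkca, Gad1, Casp1, Rpe65, Cryga, Crybb1, Krt12, Upk1b, Mylk, Btg2, Cry1, Hsp90aa1, Sag, Mak, Dbi, Car14, Glul, Tef, Map4k3 and Trappc9, and the authors did not test Trim43c, Wnt9b, Fosb or Lif. Among the same genes DESeq2 did not call Hba-a1, Bhlhe23, Casp1, Bbc3, Muc4, Upk1b, Mybpc2, Fosb, Gfap, Dbi or Lif, and limma on log2 CPM did not call Casp1, Krt12 or Fosb. Of the genes named after their values were seen, Samd7, Impg2, Socs3 and Lbh passed with sex as a covariate, and Sag, Mak, Id2, Dbi, Car14, Glul, Lif, Cd74, H2-Aa, Tef, Map4k3 and Eif2ak2 did not. When 1 library was left out, Dbi never passed (adjusted p = 0.0613 to 0.163), Lif did not pass without wild type replicate 2 or knockout replicates 2 or 3, Mak without wild type replicate 1 or knockout replicates 2 or 3, Tef without wild type replicate 2 or knockout replicate 2, Map4k3 without wild type replicate 2 or knockout replicates 2 or 3, and Eif2ak2 without wild type replicate 1 or knockout replicate 1. The gene Trappc9 passed only without wild type replicate 2, and not with sex as a covariate. Across the 14919 tested genes, which are not independent replicates, the authors' log2 fold changes and those here had a Pearson r of 0.966 and a Spearman coefficient of 0.936.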

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

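The sex covariate, the Xist-positive libraries alone, the thinning, limma on log2 CPM and limma on FPKM with the replicate block were chosen after the data were examined, and the other alternatives before. The fall of BC027072 kept its direction and its call under every alternative run, at a log2 fold change of −9.74 to −9.55 when 1 library was left out and −8.36 to −5.44 with limma on FPKM, where the pseudocount sets the size. The share of genes called near BC027072 did not differ from the rest in any window or at either threshold (Fisher exact p = 0.449 to 1). The gene counts stayed within 1.5 times with no filter (525 higher, 591 lower), a mean FPKM of at least 5 (330, 421), DESeq2 (324, 430), its size factors (429, 505), limma on log2 CPM (414, 495) and the replicate block (558, 611). Limma on log2(FPKM + 1) called 10 genes higher and 3 lower, with a pseudocount of 0.1 6 and 3, with quantile normalization 6 and 3, with median-ratio scaling 6 and 3, robust 11 and 3, and with the replicate block 51 and 50. The median SD between replicates was 0.207 on log2 FPKM and 0.0966 on log2 CPM of the counts, and limma on the counts called nearly as many genes as edgeR, so the lower counts of calls came with the FPKM values and not with limma. Sample weights in limma on FPKM gave 1016 higher genes, with 550 lower, but the weights did not converge. With the sex covariate 91 genes were higher and 144 lower, and in the Xist-positive libraries alone 96 and 149, where the lone knockout library is assumed to vary like the others. In both, fewer knockout libraries carry the comparison. Thinned to the smallest library, 203 genes were higher and 312 lower, which the lower depth brings. Leaving out 1 library gave 271 to 425 higher and 315 to 460 lower genes.

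Isoform calls fell with limma on FPKM (6 higher and 3 lower; 4 and 3 with a pseudocount of 0.1; 6 and 3 with quantile normalization; 4 and 3 with the block), with the sex covariate (15 and 49), in the Xist-positive libraries alone (7 and 27) and thinned (50 and 100). With the replicate block in edgeR 3 isoforms were higher and 2 lower, and the cause was not tested. Leaving out 1 library gave 22 to 37 higher and 19 to 73 lower isoforms. The genes shared with the authors' comparison, 672, became 12 with limma on log2(FPKM + 1), 8 with a pseudocount of 0.1, 8 with quantile normalization, 8 with median-ratio scaling, 12 robust, 92 with the block, 226 with the sex covariate, 232 in the Xist-positive libraries alone and 418 thinned. They numbered 496 to 605 when 1 library was left out. Gene lists past the threshold numbered 1 higher and 3 lower with an estimated correlation, and 8 to 10 higher and 10 to 11 lower when 1 library was left out. Of the named genes past the threshold, only Pcp2 changed sign under any alternative, to a log2 fold change of 0.0327 with sample weights (adjusted p = 0.872), and the cause was not tested.

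The replicate numbers were not read as pairs: deviations of wild type and knockout libraries with the same number correlated at 0.13, 0.07 and −0.05 across genes in the counts, which were the values tested, and knockout replicate 3 did not correlate best with its own number. Over genes of at least 10 CPM the same pairs correlated at 0.21, 0.14 and −0.05 in the counts and 0.27, 0.64 and 0.80 in the FPKM, where knockout replicate 1 correlated better with wild type replicate 2 (0.41), and the block raised the calls of limma on FPKM as given above. The cause of this difference between counts and FPKM was not tested. As a block in edgeR they raised the gene calls from 431 higher and 500 lower to 558 and 611, changed the isoform counts given above and ended no list call. Whether the numbers mark pairs thus stays open. Small changes are missed most, as the simulated recovery of 32% at 1.25-fold shows. The simulation did not vary depth, so it cannot say how much of this depth explains.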

Other observations

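The tests of depth, sex, photoreceptor share, retina share and blood were chosen after the results were seen, and the splits of the libraries and the test of the microglia share before. The 6 libraries can be split into 3 and 3 in 10 ways, so no result could be as rare as 5% of splits. Only 1 split, the genotype, called as many genes in edgeR (931, with at most 0 in any other, where at most 966 reached an unadjusted p under 0.05 against 2835). For isoforms it was again 1 split (260, with at most 1 in another), and for lists 1 (20, with at most 15 in another). The list calls at the preset correlation thus set the genotype split apart far less than the gene calls did. Each other split mixes the genotypes in unequal shares, so what its list calls reflect cannot be told.

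The 931 changed genes were set against 2 technical differences between the groups, the lower depth of the knockout libraries and the sex of the libraries. With all libraries thinned to the smallest, 515 genes were called, 490 of them among the 931, which argues against depth as the whole cause. For sex, genes called without the Xist-positive knockout library and 1 wild type library were looked up in these, which had no part in choosing them: they differed on the side of the change for 89.9%, 97.7% and 92.8% of 683, 352 and 457 genes, against 52.5%, 55.1% and 52.8% of genes at an unadjusted p over 0.5. Since all wild type libraries are Xist-positive too, this argues against sex as the whole cause, though 1 knockout library carries the comparison. The 701 genes that did not pass with the sex covariate kept a median log2 fold change of 0.37 in size, against 0.38 without it. Their median SE rose from 0.08 to 0.13. With the covariate this size rests on the Xist-positive knockout library, which had a part in calling the genes, so the kept size says little about sex. For 67 of the 931 genes the log2 fold change was smaller by 1.5 times or more with the covariate. With 1 knockout library alone, 59, 70 and 65 genes were smaller by as much for knockout replicates 1, 2 and 3. The 67 genes are thus not set apart as effects of sex. For single genes an effect of sex stays open, above all for the 701 that did not pass with the covariate.

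Photoreceptor genes mostly fell, though not all: of 61 genes in the rod, outer segment and cone lists, 45 fell, 12 did not pass and 4 rose past the threshold. Fewer photoreceptors in the eye, with rods and cones lost alike, would lower them all by about the same fold. The 4 rises (Sag, Samd7, Impg2 and Gnb3) argue against that as the whole cause. A loss of rods alone need not lower the genes of the cone list, Gnb3 among them. Sag, however, was not significant in the authors' comparison and did not pass with the sex covariate. In whole-eye RNA the cells behind each rise are not known either, which weakens this argument for any of these genes active outside photoreceptors. A lower share of retina would lower the other retinal neurons as much, but the median of the photoreceptor genes lay −0.30 from that of the 55 genes of the other neurons (−0.41 and −0.11). A permutation over genes gave p = 1e-05, the smallest that 100000 resamples can give. Genes are not independent replicates, so this p does not measure the spread between libraries. The median of the other neurons was negative too, so a lower share of retina as a part of the cause is not excluded. Whether a change in regulation, some loss of photoreceptors, a lower share of retina or a mix of these lowered the 45 stays open. Counts of photoreceptor nuclei, which could help to tell, are not in these data.

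The interferon, microglia and gliosis lists were higher by camera of limma, with 15 of 28, 16 of 30 and 16 of 27 members past the threshold, but with an estimated correlation only gliosis held (adjusted p = 0.133, 0.122 and 0.00242). Over all 85 tested genes of these lists, the median log2 fold change of the Xist-positive knockout library against wild type was 0.51. That of each wild type library against the other wild type libraries was −0.10 to 0.05. The rise was thus not confined to the male knockout libraries. The Xist-positive knockout library had a part in calling these lists higher, however, and it alone carries the comparison. Its median is therefore not an independent test of sex. More blood is argued against by the 3 red blood cell genes of the list and Beta-s, added after its value was seen, which all fell (median log2 fold change −1.31). More microglia in the eye stays a candidate explanation for the microglia genes: none of 30 fell, but their fold changes differed by more than their errors (heterogeneity Q = 220 with 29 degrees of freedom; range −0.14 to 1.11), so a single common fold did not describe them. Activation of microglia without a change in number, or both, could not be told apart from it in whole-eye RNA.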
